A study of Mus musculus with 18 samples.

How the data were processed

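RNA sequencing libraries of mouse satellite cells, the stem cells of skeletal muscle, were compared. Per the labels, the cells came from hind-limb muscles of C57BL/6 mice aged 8.5 to 9 months, were sorted as positive for VCAM1 and negative for CD31, CD45 and Sca1, and fall into 4 groups by activation and pregnancy. There were 3 non-activated libraries and 6 activated libraries from mice that were not pregnant, and 3 non-activated and 6 activated libraries from pregnant mice. That the activated cells came from muscle injured by piercing with a 23-gauge needle was read from the treatment and library protocols, which name injured and non-injured animals. The protocols state that libraries of non-injured animals were made from total RNA with ribosomal RNA depletion and libraries of injured animals after poly-A selection with another kit, so the kit goes with activation in every library. The labels do not say whether each library is a separate animal, how long after injury cells were taken, or the stage of pregnancy, and p values therefore measure the spread between these libraries only.

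Per the submitters' processing notes, the authors used cutadapt 1.12, TopHat2 2.0.14, HTSeq 0.6.0 and DESeq2 1.22.1 with genome build GRCm38, with order and settings not stated. The deposited table holds, per the file headers, raw counts per gene, normalized counts, and the authors' log2 fold changes and adjusted p values for 4 comparisons. It marks a gene without a value by a question mark, so that the columns mix numbers with text and the unit of the deposited columns was recorded as other, with the content named here. The rule by which the authors left genes without values is not stated. Of 47729 genes listed, 10792 had values, all of them protein coding, of 22048 protein-coding genes listed, and the same 36937 genes lacked a value in all value columns. The lowest of the highest counts per gene was 9 over the 18 libraries. Deposited counts were whole numbers, and each deposited normalized count was the count divided by 1 factor per library, with a largest deviation of 6.7e-10. Which libraries the authors estimated these factors over is not stated. A further 6 columns in the table, from 3 quadriceps muscle libraries of another project, were not used, since they come from whole tissue and another laboratory. Gene identifiers were looked up in a reference name table, where 10781 of the genes with values were found. Positions and genomic spans were taken from the deposited table.

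The comparisons, gene lists, named-gene rule and most of the alternatives were fixed before the data were examined. The plan named a count model for raw counts and limma-trend for normalized values. Because of the unit recorded for the deposited columns, the count models were not run and the limma-trend fit stood in for them in every comparison. Normalized counts were transformed as log2 of the value plus a pseudocount of 1. Genes were kept when their normalized count was at least 10 in at least as many libraries as the smallest group of the fit held. The limma 3.58.1 test in R 4.3.3 was used with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Activated cells were compared with non-activated cells in one fit of all 4 groups, separately in mice that were not pregnant and in pregnant mice. Pregnant and non-pregnant mice were compared within non-activated cells and within activated cells, each in a fit of the 2 groups compared, which share a library kit. The difference between the pregnancy differences was tested as an interaction in the fit of all 4 groups. Log2 changes are given with the standard error of the fit, and group levels as the mean normalized count with the standard deviation (SD). Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.

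Gene lists covered satellite cell quiescence, myogenic commitment and differentiation, mature myofibre, cell cycle S phase, cell cycle G2 and M phase, immediate early and dissociation stress, extracellular matrix, the Notch pathway, DNA methylation machinery, interferon response, inflammatory cytokines and NF-kB targets, hormone signalling (oestrogen, progesterone, prolactin and growth hormone), glucocorticoid response, oxidative phosphorylation, glycolysis, ribosome biogenesis and ribosomal proteins. Lists for other cell types covered leukocytes, endothelial cells, fibro-adipogenic progenitors, smooth muscle and pericytes, Schwann cells and erythroid cells. Lists for the kits covered replication-dependent histones, small structured RNAs and the protein-coding genes of the mitochondrial genome, and a sex check listed genes of the sex chromosomes. Each list with at least 3 members with values was tested with limma's camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and with adjustment over the lists of a comparison. Each test was repeated with the correlation estimated from the residuals, and with fry, which tests whether the genes of a list move one way on balance. Lists were counted by members past the threshold over all genes and adjusted over the list alone.

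The rule for named genes took, per comparison and direction, the 8 genes (5 for the interaction) with the largest log2 change among called genes with a mean of at least 100 normalized counts in the higher group and, outside the interaction, no overlap between the libraries compared. It added up to 4 members of each list with the smallest p values, and Pax7, Myf5, Myod1, Myog, Mki67, Vcam1, Pecam1, Ptprc, Ly6a, Dnmt1, Dnmt3a and Dnmt3b in every comparison, with predicted genes left out. Ptprc and Ly6a, which encode CD45 and Sca1, had no value in the deposited table. Where more genes qualified than could be described, the largest changes, the 12 genes above and the lists past their test came first.

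The fits were tested on simulated data with the group sizes and spreads of these libraries, in which 200 genes were changed by 1.5-fold, 2-fold or 4-fold. At 2-fold, 73.1% and 82.1% of changed genes were recovered in the comparisons of activated with non-activated cells, 38.8% and 95.5% in the pregnancy comparisons of non-activated and activated cells, and 61.2% in the interaction. Unchanged genes made up 1.2% and 3.6% of simulated calls for pregnancy, but 53.9% and 76.8% for activation and 70.5% in the interaction. With a spread estimated by group these shares were 32.1%, 41.5% and 26.6%, and with array weights 50%, 62.3% and 55.8%. These shares depend on how many genes were changed and do not carry over to real calls. A limit set for them beforehand was not met by any fit of all 4 groups. It was dropped after that result and the planned fit was kept. A list shifted by 1.3-fold was recovered in each comparison, with 0 of 23 others called, but correlated genes were not simulated.

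Alternatives were quantile normalization, no filter, pseudocounts of 0.1 and 10, array weights per group, a test for a change beyond 1.5-fold (limma's treat) in place of a change from 0, a replicate block, other sets of groups in the fit, removal of RNA classes that the kits capture differently, genes with a mean expression above the median, and each library left out in turn. Added after the data were seen were recomputed size factors, voom on the deposited counts, removal of the non-activated library of each kind of mouse with the fewest detected genes, removal of each library's trend with genomic span, and a spread by group. Counts were also compared with other splits of the same libraries. Total counts ranged from 14043324 to 24336842 per library. A count of 0 allows a true level of up to 3 counts at these depths. Reads carried no molecular identifiers, and these limits cover counting error only. No pair of libraries of the same group looked like a duplicate, with a lowest chi-squared per degree of freedom of 10.6, and pairs across groups were not checked.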

Results

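Messenger RNA of satellite cells, the stem cells that sit along muscle fibres and repair them, was measured by RNA sequencing in 18 libraries of sorted cells. Non-activated cells of mice that were not pregnant gave 3 libraries with total counts of 17903943 to 24336842, and non-activated cells of pregnant mice gave 3 libraries with 15066225 to 21626336. Activated cells, read as coming from needle-injured muscle, gave 6 libraries with 15144397 to 20500462 counts in mice that were not pregnant and 6 libraries with 14043324 to 19904594 in pregnant mice. The 20 most abundant genes took 7.29% to 10.07% of the counts of a library. Genes of the mitochondrial genome took 0.23% to 0.46% of the counts in non-activated cells, made with the total RNA kit, and 2.16% to 2.53% in activated cells, made with the poly-A kit. Across genes, libraries of the same group correlated at Pearson r = 0.979 to 0.994 in activated cells and 0.977 to 0.991 in activated cells of pregnant mice. In non-activated cells r was 0.899 to 0.949, and 0.873 to 0.891 in pregnant mice, while libraries of different kits correlated at 0.719 to 0.805. The first principal component held 64.9% of the variance and parted the libraries by activation and kit together.

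The comparison of activated with non-activated cells in mice that were not pregnant asked which genes differ after muscle injury. Myod1, the transcription factor that commits satellite cells to the muscle lineage (ENSMUSG00000009471, GRCm38 chromosome 7, 46376474 to 46379092), was 7.43-fold higher in activated cells, at 9933 ± 789 normalized counts (SD, n = 6) against 1332 ± 61.4 (SD, n = 3). Myog, which drives differentiation, was higher by a log2 change of 4.80 ± 0.52 (SE, limma adjusted p = 1.26e-07). Pax7, the transcription factor that marks the stem cell state (ENSMUSG00000028736, chromosome 4, 139737062 to 139833528), was 2.74-fold lower, at 6625 ± 1310 (SD, n = 6) against 18030 ± 3240 (SD, n = 3). Genes of cell division were higher as well. Rrm2, a subunit of ribonucleotide reductase, had a log2 change of 6.51 ± 0.37 (SE) and Ccnb2, a mitotic cyclin, one of 4.37 ± 0.25. Kif23, a motor protein of cell division, was higher by 4.14 ± 0.24, and Mki67, a proliferation marker, by 2.41 ± 0.51. Dnmt1, the maintenance DNA methyltransferase, was 4.04-fold higher. Dnmt3a, which sets new methylation marks (ENSMUSG00000020661, chromosome 12, 3806007 to 3914443), was 3.23-fold lower, at 697.4 ± 83 (SD, n = 6) against 2278 ± 529 (SD, n = 3). Tet2, an enzyme that oxidizes methylated cytosine, was lower by a log2 change of -2.62 ± 0.17 (SE). Gadd45g was higher by 2.50 ± 0.18 and Myf5, a myogenic factor, by 0.93 ± 0.18.

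The 8 called genes with the largest change towards activated cells, each with no overlap between the libraries of both groups, were Spp1, which encodes the secreted protein osteopontin, Thbs4, Actc1, Asf1b, Comp, Lgals3, Myh3 and Atp5k. Their log2 changes ran from 7.77 ± 0.57 (SE) for Atp5k to 11.01 ± 0.90 for Spp1, whose level was 4.741 ± 8.21 (SD, n = 3) in non-activated cells. Thbs4 and Comp encode matrix proteins, Actc1 and Myh3 are embryonic muscle actin and myosin, and Asf1b is a histone chaperone of dividing cells. The 8 with the largest fall were Lsmem1, Fhit, Slc7a11, Cdk8, Park2, Nkain2, Tshz2 and Immp2l, with log2 changes from -8.87 ± 0.59 for Lsmem1 to -6.26 ± 0.22 for Immp2l. Cdk8 had 172200 ± 4080 normalized counts in non-activated (SD, n = 3) and 1177 ± 99.7 in activated cells (SD, n = 6). Only total RNA libraries reached such a level, and whether it is mRNA was not tested. The genes lower in activated cells spanned a median of 71.7 kb of genome and those higher 13.7 kb. Across genes the log2 change correlated with the span at Spearman rho = -0.621, where genes are not independent replicates. Vcam1, the surface protein used in the sort, had a log2 change of -0.09 ± 0.18 and did not pass the test (adjusted p = 0.676). Neither did Pecam1, an endothelial gene, at 0.04 ± 0.46 (adjusted p = 0.941), or Dnmt3b at -0.62 ± 0.28 (adjusted p = 0.0556).

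Of the gene lists, 9 were shifted against other genes in this comparison, all towards activated cells, and each lost its call with an estimated correlation. Of 18 S phase genes tested, 17 were higher, among them Mcm5, a part of the replicative helicase, at 9.75-fold (camera adjusted p = 7.13e-06, adjusted p = 0.368 with an estimated correlation). Adjusted over the list alone, 17 were higher and 1 lower. All 16 tested genes of G2 and M phase were higher (camera adjusted p = 7.13e-06, adjusted p = 0.309 with an estimated correlation). Of 19 genes of myogenic commitment, 9 were higher and 1 lower, including Chrna1, a subunit of the muscle acetylcholine receptor, at 6.89-fold (camera adjusted p = 0.0263, adjusted p = 0.461 with an estimated correlation), or 8 and 1 adjusted over the list alone. Oxidative phosphorylation genes were higher in 60 of 63, such as Atp5g2 at 7.06-fold and Sdha at 3.62-fold, and lower in 1 (camera adjusted p = 3.44e-15, adjusted p = 0.309 with an estimated correlation), with 61 higher adjusted over the list alone. Of 15 glycolysis genes, 11 were higher, Gapdh by 12.1-fold and Ldha, lactate dehydrogenase, by 10.7-fold, and 3 lower (camera adjusted p = 0.00483, adjusted p = 0.309 with an estimated correlation). Among 65 ribosomal protein genes 63 were higher (camera adjusted p = 8.04e-18, adjusted p = 0.422 with an estimated correlation). Among 19 of ribosome biogenesis 13 were higher and 4 lower (camera adjusted p = 0.0352, adjusted p = 0.662 with an estimated correlation). All 8 mitochondrial genome genes were higher, with a median log2 change of 3.56 (camera adjusted p = 0.0003, adjusted p = 0.422 with an estimated correlation). Of 16 markers of fibro-adipogenic progenitors, matrix-producing cells of muscle, 11 were higher and 2 lower, with Col1a2 at 78.7-fold and Col1a1 at 30.4-fold (camera adjusted p = 0.0231, adjusted p = 0.309 with an estimated correlation).

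The remaining lists were not shifted against other genes in this comparison, and their counts adjusted over the list alone equalled those over all genes unless given. Quiescence genes were higher in 7 and lower in 9 of 21 (10 lower adjusted over the list alone). Notch pathway genes were higher in 5 and lower in 8 of 15, with Notch2 3.37-fold lower, and DNA methylation genes were higher in 6 and lower in 7 of 16 (8 lower adjusted over the list alone). Matrix genes were higher in 14 and lower in 5 of 22, with Lox, which crosslinks collagen, 10.1-fold higher and Lama2, a laminin of the muscle basement membrane, 5.41-fold lower. Leukocyte markers were higher in 6 of 8, among them Lyz2, lysozyme, at 421.6 ± 102 (SD, n = 6) against 15.46 ± 13.6 (SD, n = 3), and Cd14, a receptor of myeloid cells, at 33.9-fold. Mature myofibre genes were higher in 5 of 11 (3 adjusted over the list alone) and endothelial genes in 4, with 1 lower, of 11. The counts were 6 higher of 11 for smooth muscle and pericytes and 3 of 8 for Schwann cells, and erythroid genes, too few for a list test, had 1 higher and 1 lower of 2. Immediate early genes were higher in 10 and lower in 2 of 24, interferon response genes in 11 and 4 of 21, and inflammatory genes in 7 and 5 of 15. Hormone signalling genes were higher in 2 and lower in 4 of 11, and glucocorticoid response genes in 8 and 5 of 15. Replication-dependent histone genes, whose transcripts mostly lack poly-A tails, were higher in 3 and lower in 4 of 8 (5 lower adjusted over the list alone), with a median log2 change of -2.53. None of the small structured RNAs had a value. For the Notch list the median was -0.62, the mean 0.17 and the test downward, and for DNA methylation they were -0.53, 0.10 and downward. For the inflammatory list they were 0.53, 0.65 and upward, while fry pointed downward.

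The limma test called 7806 of 10751 genes in mice that were not pregnant, 4189 higher and 3617 lower in activated cells, of which 2870 and 2348 changed at least 2-fold. Without adjustment 8009 genes had a p under 0.05. The authors' deposited table held 7933 genes past the same threshold, including 97.6% of those called here, all with the same sign. The kit differed along with activation in every library, so that no within-kit value can be had and the differences cannot be told apart from those of the kit. In simulated data this fit called 180 of 10485 unchanged genes, or 1.72%. A limma test for a change beyond 1.5-fold, in place of a change from 0, called 5110 genes. With a spread by group the calls of Actc1 (adjusted p = 0.215), Comp (adjusted p = 0.0647), Myh3 (adjusted p = 0.233), Lyz2 (adjusted p = 0.181) and Cd14 (adjusted p = 0.0961) were lost. With 1 non-activated library left out the fold moved by over 1.5 times for 13 of the 41 called genes named. The log2 change of Spp1 was 12.32 without nonactivated replicate 3 and 10.35 without replicate 1 or 2, and that of Thbs4 6.71 without replicate 1 and 11.17 without replicate 2. Actc1 had 11.24 without replicate 2 and 8.01 without replicate 1 or 3. Cd14 had 3.86 and Lyz2 4.10 without replicate 1, and 5.86 and 6.47 without replicate 3. The others were Asf1b, Comp, Lgals3, Myh3, Atp5k, Myog, Rrm2 and Mki67. The ribosome biogenesis list lost its shift without nonactivated replicate 2 (camera adjusted p = 0.069) or 3 (0.0783). The matrix list gained one in 3 fits with 1 library left out (down to 0.0338) and the immediate early list without activated replicate 1 (0.031). The direction of Lama2 and Myf5 turned when each library's trend with genomic span was taken out.

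The same question was asked of activated and non-activated cells in pregnant mice. Myog was 50.5-fold higher, at 6151 ± 2750 normalized counts (SD, n = 6) against 126.4 ± 70.2 (SD, n = 3), and Myod1 2.10-fold higher (limma adjusted p = 8.69e-07), from a level of 5039 ± 465 in non-activated cells. Top2a, the topoisomerase of dividing cells, was higher by a log2 change of 5.94 ± 0.41 (SE). Birc5, a part of the chromosomal passenger complex, was higher by 7.10 ± 0.47, Ccnb2 by 4.92 ± 0.25 and Mki67 by 3.62 ± 0.51. Uhrf1, which brings Dnmt1 to replicating DNA, was higher by 6.76 ± 0.36, Dnmt1 by 2.45 ± 0.21 and Dnmt3b, a methyltransferase that sets new marks, by 1.02 ± 0.28. Dnmt3a was 1.40-fold lower (adjusted p = 0.0021). Pax7 was 1.70-fold lower and Vcam1 1.60-fold lower, and Myf5 was 1.56-fold higher. The direction of Pax7, Myod1, Myf5 and Dnmt3a in pregnant mice turned when each library's trend with genomic span was taken out, with Pax7 no longer past the test. Pecam1 had a log2 change of 0.35 ± 0.46 that did not pass.

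The largest changes towards activated cells in pregnant mice ran from a log2 change of 7.81 ± 0.80 (SE) for Asf1b to 8.52 ± 0.91 for Cks1b, a cell cycle kinase subunit. The others were those of Gtf3c2, Mgp, a matrix protein, Mmp3, a matrix protease, Angptl7, Lyz2 and Cdc6, a replication licensing factor. In the other direction they included those of Cdk8 at -7.96 ± 0.19, Cmss1, Fhit, Park2, Kcnq1, Hist1h1e, a linker histone, at -6.45 ± 0.32, and Nkain2 at -6.31 ± 0.27. Fn1, the matrix protein fibronectin, was 28.0-fold higher, Col1a1 51.8-fold and Col1a2 82.8-fold. Lyz2 stood at 1627 ± 928 (SD, n = 6) against 9.722 ± 9.45 (SD, n = 3), and H2-Ab1, a class II antigen-presenting gene, at 222.7 ± 149 against 3.718 ± 6.44. Genes higher in activated cells of pregnant mice spanned a median of 14.5 kb and those lower 69.3 kb.

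In pregnant mice 9 lists were shifted towards activated cells, none of them with an estimated correlation. Leukocyte markers were higher in 8 of 8, with a median log2 change of 6.04 (camera adjusted p = 0.00804, adjusted p = 0.39 with an estimated correlation). Fibro-adipogenic markers were higher in 13 of 16 (camera adjusted p = 0.00235, adjusted p = 0.197 with an estimated correlation). S phase genes were higher in 17 of 18, Mcm5 by a log2 change of 4.00 ± 0.23 (camera adjusted p = 5.58e-07, adjusted p = 0.268 with an estimated correlation), or 18 adjusted over the list alone. G2 and M phase genes were higher in 16 of 16 (camera adjusted p = 5.58e-07, adjusted p = 0.197 with an estimated correlation). Myogenic commitment genes were higher in 12 and lower in 1 of 19 (camera adjusted p = 0.0352, adjusted p = 0.469 with an estimated correlation). Oxidative phosphorylation genes were higher in 59 and lower in 1 of 63 (camera adjusted p = 8.47e-13, adjusted p = 0.197 with an estimated correlation). Glycolysis genes were higher in 12, Gapdh by 9.26-fold, and lower in 2 of 15 (camera adjusted p = 0.00354, adjusted p = 0.197 with an estimated correlation). Ribosomal protein genes were higher in 60 and lower in 3 of 65 (camera adjusted p = 3.23e-14, adjusted p = 0.469 with an estimated correlation), or 61 and 3 adjusted over the list alone. All 8 mitochondrial genome genes were higher (camera adjusted p = 0.000315, adjusted p = 0.426 with an estimated correlation).

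Lists not shifted in pregnant mice had the same counts adjusted over the list alone unless given. They were quiescence with 4 higher and 8 lower of 21, mature myofibre with 6 higher of 11, immediate early with 8 higher and 1 lower of 24, and endothelial with 5 and 1 of 11. Smooth muscle and pericytes had 8 higher of 11 (8 higher and 1 lower adjusted over the list alone), Schwann cells 6 higher of 8, and erythroid cells 0 of 2. Matrix genes were higher in 14 and lower in 5 of 22, Notch pathway genes in 5 and 5 of 15, and DNA methylation genes in 7 and 7 of 16. For interferon response they were 6 and 7 of 21 and for inflammatory genes 5 and 7 of 15. Hormone signalling genes were higher in 3 and lower in 3 of 11, glucocorticoid response genes in 7 and 5 of 15, ribosome biogenesis genes in 10 and 4 of 19, and histone genes in 2 and 4 of 8. The median, mean and test differed in sign for Notch genes (-0.22, 0.31, downward), DNA methylation genes (-0.26, 0.65, downward, with fry upward), interferon genes (0.09, 0.18, downward) and inflammatory genes (-0.03, 0.21, downward).

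The limma test called 7832 of 10751 genes in pregnant mice, 4328 higher and 3504 lower, of which 3009 and 2112 changed at least 2-fold. Without adjustment 8028 had a p under 0.05. The authors' deposited table held 7805 such genes, including 95.9% of those called here, with the same sign. Across genes, the log2 changes in pregnant mice correlated with those in mice that were not pregnant at Pearson r = 0.856 and Spearman rho = 0.86. The called genes were higher in both for 3447 genes, where independence would give 1686.4, lower in both for 3047 against 1178.9, and opposite for 98. Both comparisons share the kit difference, which alone can give a high correlation. In simulated data the fit called 613 of 10478 unchanged genes, or 5.85%. The test for a change beyond 1.5-fold called 4984 genes. With 1 non-activated library left out the fold moved by over 1.5 times for 14 of the 34 called genes named. The log2 change of Mgp was 6.35 without nonactivated_pregnant replicate 3 and 9.46 without replicate 2, and that of Lyz2 6.60 without replicate 2 and 8.75 without replicate 3. The others were Cks1b, Gtf3c2, Mmp3, Angptl7, Cdc6, Asf1b, Myog, Birc5, Top2a, Uhrf1, H2-Ab1 and Mki67. The myogenic commitment list lost its shift without nonactivated_pregnant replicate 1 (camera adjusted p = 0.0766) or 3 (0.0524), and the matrix list gained one in 4 fits (down to 0.0188). Calls were lost with a spread by group for Mmp3 (adjusted p = 0.218), Angptl7 (adjusted p = 0.317), Lyz2 (adjusted p = 0.151), Cdc6 (adjusted p = 0.12), H2-Ab1 (adjusted p = 0.21) and Dnmt3b (adjusted p = 0.0732). With quantile normalization they were lost for Pax7 (log2 change -0.34, adjusted p = 0.0616), Vcam1 (-0.32, adjusted p = 0.118) and Dnmt3b (0.26, adjusted p = 0.386). With array weights they were lost for Pax7 (adjusted p = 0.0781), Myf5 (adjusted p = 0.141), Vcam1 (adjusted p = 0.108) and Dnmt3a (adjusted p = 0.0858).

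Pregnant mice were then compared with non-pregnant mice in non-activated cells, within the total RNA kit. Myod1 rose 3.77-fold, to 5039 ± 465 normalized counts (SD, n = 3) from 1332 ± 61.4 (SD, n = 3), a log2 change of 1.92 ± 0.16 (SE, limma adjusted p = 2.06e-05). Tnc, the matrix protein tenascin C (ENSMUSG00000028364, chromosome 4, 63959785 to 64047015), rose 7.99-fold, to 7290 ± 1880 from 918.2 ± 248. Ccl2, a chemokine that attracts monocytes (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453), rose 9.49-fold, to 3185 ± 1530 from 339.9 ± 164. Greb1, a target of the oestrogen receptor (ENSMUSG00000036523, chromosome 12, 16670615 to 16800886), fell 7.30-fold, to 986.5 ± 174 from 7714 ± 3730. Dnmt3a fell 2.05-fold, to 1095 ± 96 from 2278 ± 529 (adjusted p = 0.00706). Pax7 fell 1.55-fold, to 11480 ± 217 from 18030 ± 3240 (adjusted p = 0.041). Vcam1 rose 1.97-fold (adjusted p = 0.0177).

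The other genes with the largest rise in pregnant, non-activated cells were Tnfaip2, Rnd1, Hmox1, which degrades haem, Sipa1l2, Angptl4, which inhibits lipoprotein lipase, and Enc1, with log2 changes from 2.69 ± 0.62 (SE) for Enc1 to 3.02 ± 0.51 for Tnfaip2. The other large falls were those of Tmem266, Amacr, Uhrf1, Car12, a carbonic anhydrase, Dclk3, Ksr2 and Gpam, an enzyme of triglyceride synthesis, from -4.08 ± 0.74 for Tmem266 to -2.19 ± 0.28 for Gpam. For each of these the 3 libraries of one group lay above the 3 of the other. The calls of Amacr and Uhrf1 were lost in 5 of 6 fits with 1 library left out, up to adjusted p = 0.155 and 0.234. They held only without nonactivated_pregnant replicate 3. Leaving out 1 library moved the fold by over 1.5 times for Amacr (log2 change -2.43 without nonactivated_pregnant replicate 1 and -4.35 without replicate 3), Uhrf1 (-3.46 without the latter), Tmem266 (-4.77 without nonactivated replicate 3) and Tnfaip2 (2.35 without nonactivated replicate 1). The call of Enc1 was lost without nonactivated_pregnant replicate 1 or 2 (up to adjusted p = 0.131). That of Tmem266 was lost without nonactivated replicate 2 (adjusted p = 0.0656). Pax7 kept its call only without nonactivated replicate 1, with adjusted p up to 0.202 otherwise. Vcam1 lost it without nonactivated replicate 1 or nonactivated_pregnant replicate 2 or 3 (up to adjusted p = 0.095). Myf5 had a log2 change of 0.32 ± 0.22, Myog -1.50 ± 0.69, Mki67 -0.82 ± 0.66, Pecam1 -0.70 ± 0.33, Dnmt1 -0.67 ± 0.24 and Dnmt3b -1.47 ± 0.67, none of which passed the test.

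In non-activated cells 7 lists were shifted by pregnancy, none of them with an estimated correlation. Inflammatory genes and NF-kB targets rose in 5 of 14, or 10 adjusted over the list alone, with a median log2 change of 0.86 (camera adjusted p = 4.67e-09, adjusted p = 0.389 with an estimated correlation). Beside Ccl2 they included Cxcl1, a chemokine for neutrophils, at 5.22-fold, Icam1, an adhesion molecule, at 3.04-fold, and Tnfaip3, which restrains NF-kB, at 1.95-fold. Interferon response genes rose in 2 of 21, or 6 adjusted over the list alone, Gbp2 by 3.68-fold and Ifi27 by 2.08-fold (camera adjusted p = 3.02e-05, adjusted p = 0.171 with an estimated correlation). Matrix genes rose in 4 of 22, or 8 adjusted over the list alone, with Vcan, a proteoglycan, at 4.89-fold, Lox at 2.90-fold and Thbs1 at 2.28-fold (camera adjusted p = 0.00011, adjusted p = 0.655 with an estimated correlation). Ribosome biogenesis genes were called in 0 of 19, or 2 higher adjusted over the list alone, at a median log2 change of 0.48 (camera adjusted p = 0.000214, adjusted p = 0.863 with an estimated correlation). Ribosomal protein genes were called in 0 of 65 at a median of 0.16 (camera adjusted p = 0.0155, adjusted p = 0.863 with an estimated correlation). DNA methylation genes fell in 2 of 16, Dnmt3a and Uhrf1 (camera adjusted p = 0.0341, adjusted p = 0.405 with an estimated correlation). S phase genes were called in 0 of 18 at a median of -0.48 (camera adjusted p = 0.0341, adjusted p = 0.519 with an estimated correlation). Leukocyte markers, with a median of -1.06, were called in 0 of 6. Without nonactivated_pregnant replicate 3 the matrix list lost its shift (adjusted p = 0.0648), as did ribosomal protein genes (adjusted p = 0.961, at a median of -0.01), DNA methylation and S phase genes (adjusted p = 0.0549 each). Ribosomal protein genes lost it also without nonactivated replicate 2 or 3 or nonactivated_pregnant replicate 2 (up to adjusted p = 0.369). DNA methylation genes did so without nonactivated replicate 2 or nonactivated_pregnant replicate 1 (up to adjusted p = 0.0889), and S phase genes without either of these or nonactivated replicate 1 (up to adjusted p = 0.108).

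Lists not shifted in non-activated cells had the same counts adjusted over the list alone unless given. Quiescence genes rose in 1 and fell in 3 of 21 (2 and 3 adjusted over the list alone), Foxo1 by a log2 change of -0.92 ± 0.15 (SE), Heyl by -0.90 ± 0.19 and Sdc4 by 0.77 ± 0.18. Immediate early genes rose in 2 and fell in 3 of 24 (4 and 7 adjusted over the list alone), Myc 2.29-fold higher and Fos 2.36-fold lower. Hormone signalling genes rose in 2 and fell in 2 of 11 (3 and 2 adjusted over the list alone), Igfbp5 by 1.51 ± 0.20, Cish, a target of STAT5, by 1.56 ± 0.33, and Wnt4 by -1.59 ± 0.36. Glucocorticoid response genes rose in 4 and fell in 2 of 15 (5 and 2 adjusted over the list alone), with Zbtb16 2.44-fold lower. Notch pathway genes fell in 2 of 13 (1 higher and 2 lower adjusted over the list alone), glycolysis genes rose in 1, Hk2, and fell in 1 of 15. Myogenic commitment genes rose in 1 of 17, Myod1, and Schwann cell genes fell in 1 of 6, Ngfr, by -1.86 ± 0.37. Mature myofibre genes were called in 0 of 10 (1 lower adjusted over the list alone), G2 and M phase in 0 of 16, endothelial in 0 of 11, fibro-adipogenic in 0 of 16 and smooth muscle and pericyte in 0 of 10. Erythroid genes were called in 0 of 1 (1 lower adjusted over the list alone), oxidative phosphorylation genes in 0 of 63, histone genes in 0 of 8 (1 higher adjusted over the list alone) and mitochondrial genome genes in 0 of 8. Some lists were shifted with 1 library left out, endothelial genes downward without nonactivated replicate 1 (camera adjusted p = 0.00217, median -2.04 against -0.27 with all libraries) and quiescence genes downward without nonactivated_pregnant replicate 3 (0.0171). Without nonactivated_pregnant replicate 1 mitochondrial genome genes (0.0044) and oxidative phosphorylation genes (0.0427) were shifted upward. The calls of Heyl, Sdc4, Ifi27, Cish, Wnt4 and Zbtb16 were lost without nonactivated_pregnant replicate 2 and in up to 4 of the other fits with 1 library left out, at adjusted p up to 0.123. That of Ngfr was lost without nonactivated replicate 2 (adjusted p = 0.085). The median, mean and test differed in sign for myogenic commitment (-0.05, -0.10, upward), smooth muscle and pericytes (0.06, -0.10, upward), hormone signalling (-0.07, 0.04, upward) and histones (-0.39, -0.29, upward).

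The limma test called 483 of 10447 genes in non-activated cells, 301 higher and 182 lower in pregnant mice, of which 167 and 97 changed at least 2-fold. Without adjustment 1903 had a p under 0.05. The genes lower spanned a median of 131.7 kb and those higher 29 kb, against 27.8 kb for all genes tested. With quantile normalization 51.5% of 505 called genes were higher, against 62.3% here. With it the calls of Amacr (adjusted p = 0.056) and Vcam1 (adjusted p = 0.0524) were lost. The authors' deposited table held 2812 such genes, including 98.8% of those called here, with the same sign. The count fell to 237 without nonactivated replicate 2, to 247 without nonactivated_pregnant replicate 2 and to 117 without the library of each group with the fewest detected genes. In that last fit 18 of the 39 called genes named for this comparison lost their call, among them Dnmt3a (adjusted p = 0.105), Pax7 (adjusted p = 0.0904) and Tnfaip3 (adjusted p = 0.12). The count was 39 in the test for a change beyond 1.5-fold, which large changes with a wide spread do not pass either, and 2485 with all 4 groups in the fit.

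**Figure D1:**
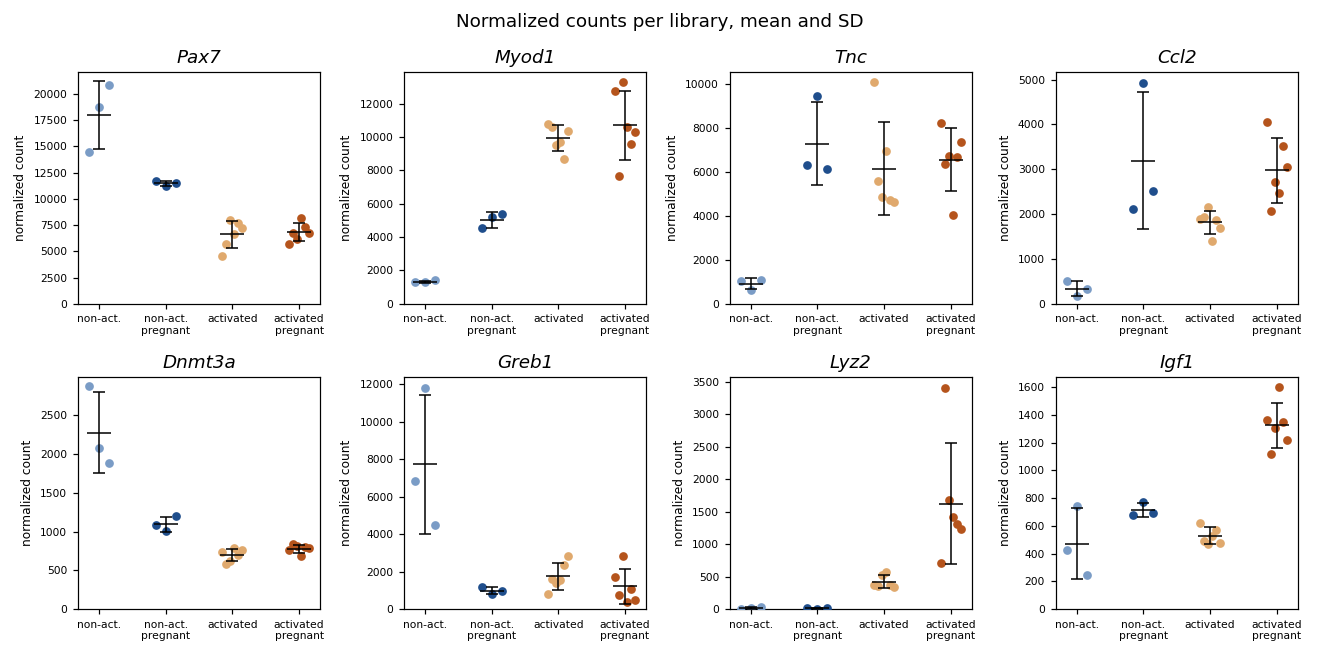
Normalized counts of 8 genes in each library (points) of the 4 groups, on a linear axis, with the group mean and SD (bars). In non-activated cells Myod1, Tnc and Ccl2 lie higher and Greb1 and Dnmt3a lower in pregnant mice, and in activated cells Lyz2 and Igf1 lie higher.

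Pregnant mice were compared with non-pregnant mice in activated cells as well, within the poly-A kit. Igf1, a growth factor for muscle (ENSMUSG00000020053, chromosome 10, 87858265 to 87937042), rose 2.51-fold, to 1326 ± 164 normalized counts (SD, n = 6) from 528.2 ± 60.4 (SD, n = 6), a log2 change of 1.32 ± 0.09 (SE, limma adjusted p = 3.59e-06). Genes of the matrix rose, with Loxl2, which crosslinks collagen, 2.06-fold higher at 967.3 ± 108 against 468.8 ± 41.8. Mmp14, a membrane-bound matrix protease, was 1.53-fold higher and Col6a1 1.68-fold higher. H2-Aa, a class II gene, rose 5.06-fold and Cd74, the chaperone of class II molecules, 4.43-fold, calls that were lost with all 4 groups in the fit, as was that of Lyz2 (up to adjusted p = 0.17). Lyz2 (ENSMUSG00000069516, chromosome 10, 117277334 to 117282274) rose 3.51-fold, to 1627 ± 928 from 421.6 ± 102. Hes1, a target of Notch, fell 1.83-fold, to 507.8 ± 85 from 925.1 ± 136, and Ddit4, an inhibitor of mTOR signalling, fell 2.00-fold. Pax7 had a log2 change of 0.06 ± 0.13, Myod1 0.09 ± 0.12, Myf5 0.03 ± 0.13, Myog -0.64 ± 0.27 and Mki67 0.39 ± 0.15, none of which passed the test.

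The other genes with the largest rise in activated cells of pregnant mice were Col22a1, Syk, a kinase of immune receptors, H2-Eb1, Pi16 and Ctss, a protease of antigen-presenting cells, with log2 changes from 1.93 ± 0.30 (SE) for Ctss to 2.25 ± 0.46 for Col22a1. The other large falls were those of Hspb8, a small heat shock protein, Pdp2, Bola1, Rpp38, Rpp25l and Taco1, from -0.82 ± 0.16 for Hspb8 to -0.68 ± 0.12 for Taco1. For each of these genes the 6 libraries of one group lay above the 6 of the other. Vcam1 rose 1.31-fold (adjusted p = 0.0278), a call lost in 5 of 12 fits with 1 library left out. These were without activated replicate 2 or 4 or activated_pregnant replicate 4, 5 or 6 (up to adjusted p = 0.0592). Dnmt1 had a log2 change of -0.23 ± 0.16, Dnmt3a 0.17 ± 0.08, Dnmt3b 0.17 ± 0.11 and Pecam1 -0.39 ± 0.41, none of which passed the test. The genes higher in pregnant mice spanned a median of 49.9 kb and those lower 14 kb, with Spearman rho = 0.302 across genes between log2 change and span.

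In activated cells 11 lists were shifted by pregnancy, none of them with an estimated correlation. Leukocyte markers rose in 8 of 8 at a median log2 change of 1.66, Cd14 by 2.86-fold (camera adjusted p = 4.47e-07, adjusted p = 0.352 with an estimated correlation). This rise stood beside those of the lists that follow. Matrix genes rose in 16 of 22, or 18 adjusted over the list alone (camera adjusted p = 7.09e-10, adjusted p = 0.189 with an estimated correlation). Fibro-adipogenic markers rose in 11 of 16, Col1a1 by 2.16-fold, Col3a1 by 1.66-fold and Pi16 by 3.94-fold (camera adjusted p = 3.61e-06, adjusted p = 0.203 with an estimated correlation). Smooth muscle and pericyte markers rose in 4 of 11, Cspg4 by 1.74-fold and Pdgfrb by 1.47-fold (camera adjusted p = 0.0234, adjusted p = 0.652 with an estimated correlation). Inflammatory genes rose in 9 of 15, or 10 adjusted over the list alone, Il1b by 2.98-fold and Icam1 by 1.83-fold (camera adjusted p = 4.84e-06, adjusted p = 0.189 with an estimated correlation). Interferon response genes rose in 5 of 21, or 4 adjusted over the list alone, Cxcl10 by 2.01-fold and Stat2 by 1.55-fold (camera adjusted p = 0.0163, adjusted p = 0.86 with an estimated correlation). Without activated_pregnant replicate 4 the interferon list lost its shift (camera adjusted p = 0.118), with a mean log2 change of 0.13 against 0.25 with all libraries. So did the smooth muscle and pericyte list (camera adjusted p = 0.118, mean 0.25 against 0.42), which lost it without activated replicate 1 as well (camera adjusted p = 0.0539). With the S phase list lost too and histone genes gained, 9 lists were shifted without activated_pregnant replicate 4.

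Genes of energy metabolism and of the ribosome fell in activated cells of pregnant mice, by less. Oxidative phosphorylation genes fell in 48 of 63, or 53 adjusted over the list alone, at a median log2 change of -0.26 (camera adjusted p = 1.4e-14, adjusted p = 0.477 with an estimated correlation). Among them were Ndufv1 of complex I at 2137 ± 74.5 (SD, n = 6) against 2679 ± 211 and Ndufs7, 1.39-fold lower. Glycolysis genes fell in 8 of 15 (1 higher and 10 lower adjusted over the list alone), Ldha by 1.37-fold and Slc16a3, which exports lactate, by 1.53-fold (camera adjusted p = 0.00392, adjusted p = 0.365 with an estimated correlation). Ribosome biogenesis genes fell in 9 of 19, or 13 adjusted over the list alone, Nop2 by 1.35-fold (camera adjusted p = 1.24e-05, adjusted p = 0.652 with an estimated correlation). Ribosomal protein genes fell in 25 of 65, or 44 adjusted over the list alone, Rps2 by 1.26-fold (camera adjusted p = 6.37e-12, adjusted p = 0.652 with an estimated correlation). S phase genes fell in 2 of 18, or 1 adjusted over the list alone, Ccne1, a cyclin of S phase entry, by 1.53-fold (camera adjusted p = 0.00596, adjusted p = 0.86 with an estimated correlation). Without activated_pregnant replicate 4 the S phase list was not shifted (camera adjusted p = 0.0554), at a mean log2 change of -0.17 against -0.29 with all libraries. After each library's trend with genomic span was taken out, 20 of the 48 oxidative phosphorylation calls were left, at a median log2 change of -0.18 ± 0.08 (SD over genes) against -0.29 ± 0.05 before.

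Lists not shifted in activated cells had the same counts adjusted over the list alone unless given. Hormone signalling genes rose in 2 and fell in 2 of 11, with Igf1 among the first and Wnt4 2.49-fold lower. Notch pathway genes rose in 2 and fell in 2 of 15, with Heyl 1.52-fold lower, and DNA methylation genes in 3 and 1 of 16, with Tet2 1.72-fold higher. G2 and M phase genes rose in 2 and fell in 1 of 16, Cenpf by a log2 change of 0.53 ± 0.17 (SE) and Plk1 by -0.54 ± 0.17. These calls were lost in 8 and 5 of 12 fits with 1 library left out, without activated replicate 2 and activated_pregnant replicate 4 among others (up to adjusted p = 0.0613 and 0.0851). Quiescence genes fell in 3 of 21, myogenic commitment genes in 1 of 19 (0 adjusted over the list alone), and glucocorticoid response genes rose in 1 and fell in 1 of 15. Immediate early genes rose in 2 and fell in 4 of 24, Btg2 by 1.96-fold, and histone genes fell in 2 of 5. Mature myofibre genes were called in 0 of 10, endothelial in 0 of 11, Schwann cell in 0 of 8, mitochondrial genome in 0 of 8 and erythroid in 0 of 1 (1 lower adjusted over the list alone). Without activated replicate 1 the immediate early list was shifted downward (camera adjusted p = 5.29e-05, median -0.47 against -0.25 with all libraries). For G2 and M phase the median was -0.07, the mean 0.01 and the test downward.

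The limma test called 2883 of 10499 genes in activated cells, 1473 higher and 1410 lower in pregnant mice, of which 170 and 21 changed at least 2-fold. Without adjustment 4326 had a p under 0.05. The authors' deposited table held 1036 such genes, including 35.2% of those called here, with the same sign. Of their genes 762 were higher and 274 lower. With all 4 groups in the fit 578 genes were called, 481 higher and 97 lower. The test for a change beyond 1.5-fold called 13, all higher, which large changes with a wide spread do not pass either. Of 44 called genes named for this comparison, 25 lost their call with all 4 groups in the fit. Among them were H2-Aa (adjusted p = 0.0764), Cd74 (adjusted p = 0.17), H2-Eb1 (adjusted p = 0.173), Lyz2 (adjusted p = 0.155), Cd14 (adjusted p = 0.293), Ctss (adjusted p = 0.12) and Syk (adjusted p = 0.0851). Il1b (adjusted p = 0.178), Cxcl10 (adjusted p = 0.0663), Pi16 (adjusted p = 0.192), Cspg4 (adjusted p = 0.0551), Pdgfrb (adjusted p = 0.197) and Vcam1 (adjusted p = 0.142) lost it too. So did the falls of Ndufv1, Slc16a3, Nop2, Rps2, Ccne1, Hspb8, Pdp2, Bola1, Rpp25l and Taco1, and Cenpf and Plk1.

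**Figure D2:**
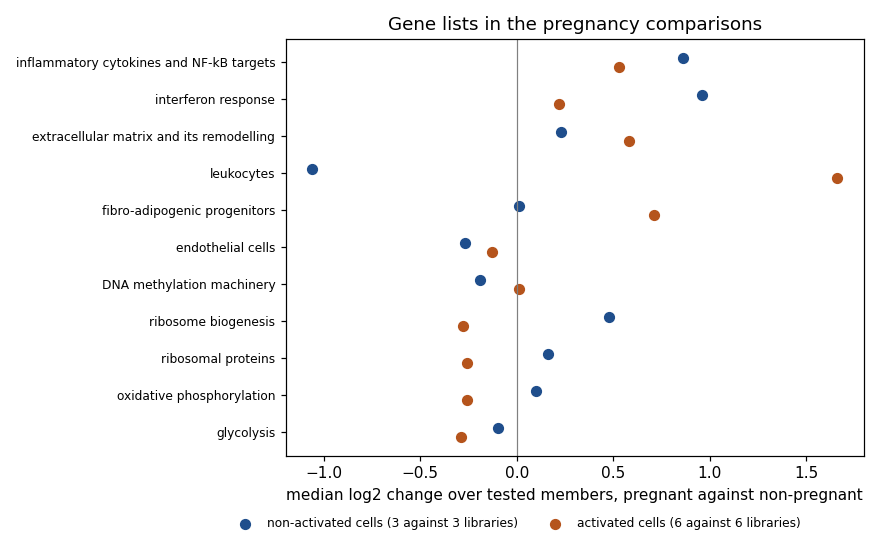
Median log2 change between pregnant and non-pregnant mice of 11 gene lists, in non-activated cells (3 against 3 libraries) and in activated cells (6 against 6 libraries). Leukocyte markers lie at 1.66 in activated and -1.06 in non-activated cells, and the inflammatory list lies above 0 in both.

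Whether pregnancy went with the same genes in both kinds of cells was compared across genes. Icam1 rose in both, by a log2 change of 1.61 in non-activated and 0.88 in activated cells. So did Cxcl1 (2.39 and 0.77), Ccl2 (3.25 and 0.69), Gbp5, an interferon-induced GTPase (1.86 and 0.95), and H2-Q7, a class I gene (2.26 and 1.34). Wnt4 fell in both (-1.59 and -1.32). Of these, Gbp5 and H2-Q7 were chosen after their values were seen. Genes called higher in both numbered 111, where independence would give 41.4, genes lower in both 38 against 24.6, and 13 were called in opposite directions. Across all 10257 genes tested in both, the log2 changes correlated at Pearson r = 0.098 and Spearman rho = 0.114. The r had a jackknife standard error of 0.076 over libraries, and it ran from 0.045 to 0.124 with 1 library left out. Genes are not independent replicates, and the numbers of libraries differ between both comparisons.

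The interaction asked whether the pregnancy difference itself differed between activated and non-activated cells. The difference for Myod1 was lower in activated cells by a log2 value of -1.83 ± 0.19 (SE, limma adjusted p = 2.3e-05). Its level in pregnant and other mice was 5039 ± 465 against 1332 ± 61.4 normalized counts in non-activated cells (SD, n = 3 each) and 10710 ± 2090 against 9933 ± 789 in activated cells (SD, n = 6 each). It was lower by -2.87 ± 0.36 for Tnc and by -1.72 ± 0.30 for Vcan, both of the matrix. It was higher by 1.20 for Dnmt3a (adjusted p = 0.000682), 1.64 ± 0.40 for Dnmt3b and 2.48 ± 0.51 for Uhrf1. The largest positive values were those of Ifi205, an interferon-induced gene, at 5.63 ± 1.02, Xirp2, H2-Ab1, AI607873 and Tmem204 at 4.58 ± 1.08. The largest negative ones were those of Spp1 at -5.79 ± 1.27, Hspb8, Pgf, a placental growth factor, Dusp4 and Esm1 at -3.83 ± 1.09. These sizes and their order depend on single non-activated libraries. With 1 left out the values ran from -7.10 to -4.07 for Spp1, -6.37 to -3.67 for Hspb8, -5.18 to -3.29 for Pgf, -4.96 to -2.19 for Dusp4 and -5.10 to -2.24 for Esm1. For the positive ones they ran from 4.88 to 7.13 for Ifi205, 4.71 to 7.39 for Xirp2, 4.74 to 6.54 for H2-Ab1, 3.29 to 5.95 for AI607873 and 3.73 to 6.28 for Tmem204. Uhrf1 had 3.09 without nonactivated_pregnant replicate 3, Birc5 2.05 and 3.75 without nonactivated_pregnant replicate 2 and 3, and Cenpa -1.32 without nonactivated replicate 1. Other called list members were Cdkn1a, a cell cycle inhibitor, at -0.96 ± 0.27, Birc5 at 2.90 ± 0.66, Cenpa, a centromere histone, at -2.17 ± 0.59, and Ndufa9 of complex I at -0.84 ± 0.17. Pax7 had 0.69 ± 0.22 (adjusted p = 0.0449), a call lost in 12 of 18 fits with 1 library left out, without any of the 3 nonactivated_pregnant libraries among others, up to adjusted p = 0.111. The call of Cdkn1a was lost without nonactivated_pregnant replicate 3 (adjusted p = 0.0597), as was that of Esm1 (adjusted p = 0.0541). That of Dusp4 was lost without nonactivated_pregnant replicate 2 (adjusted p = 0.0547). Vcam1 at -0.59 ± 0.26, Myf5 at -0.29 ± 0.25, Myog at 0.86 ± 0.74, Mki67 at 1.21 ± 0.72, Dnmt1 at 0.43 ± 0.29 and Pecam1 at 0.31 ± 0.66 did not pass.

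For 7 lists the pregnancy difference differed between both kinds of cells, for none with an estimated correlation. It was higher in activated cells for leukocyte markers, 3 of 8 members called higher or 4 adjusted over the list alone (camera adjusted p = 0.0147, adjusted p = 0.669 with an estimated correlation). The same held for DNA methylation genes, 3 of 16, namely Dnmt3a, Dnmt3b and Uhrf1 (camera adjusted p = 0.0147, adjusted p = 0.177 with an estimated correlation). It was lower for interferon response genes, 3 of 21 or 8 adjusted over the list alone (camera adjusted p = 0.00894, adjusted p = 0.669 with an estimated correlation). It was lower too for inflammatory genes, 3 of 15, namely Ccl2, Cxcl1 and Icam1 (camera adjusted p = 0.0225, adjusted p = 0.669 with an estimated correlation). Oxidative phosphorylation genes were lower in 8 and higher in 1 of 63 (camera adjusted p = 0.000121, adjusted p = 0.669 with an estimated correlation). Ribosome biogenesis genes were lower in 11 of 19, or 14 adjusted over the list alone (camera adjusted p = 3.27e-08, adjusted p = 0.669 with an estimated correlation). Ribosomal protein genes were lower in 8 of 65, or 7 adjusted over the list alone (camera adjusted p = 7.42e-09, adjusted p = 0.783 with an estimated correlation). The leukocyte list lost its shift without nonactivated replicate 3 or nonactivated_pregnant replicate 3 (up to camera adjusted p = 0.178), and the DNA methylation list without nonactivated_pregnant replicate 1 (0.0739). The inflammatory list lost it without nonactivated replicate 2 or nonactivated_pregnant replicate 1 or 2 (up to 0.177). Some lists gained a shift with 1 library left out, G2 and M phase genes in 4 fits (down to 0.0183, without nonactivated replicate 3), fibro-adipogenic genes (0.0467) without the same library, endothelial genes (0.0433) without nonactivated replicate 1, immediate early genes (0.0142) without activated replicate 1 and mitochondrial genome genes (0.0203) without nonactivated_pregnant replicate 1.

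Lists not shifted in the interaction had the same counts adjusted over the list alone unless given. They were quiescence with 2 higher and 1 lower of 21 (2 and 2 adjusted over the list alone), myogenic commitment with 1 and 2 of 19, and mature myofibre with 1 and 1 of 11 (2 and 1 adjusted over the list alone). S phase had 3 higher and 1 lower of 18, G2 and M phase 1 and 1 of 16, immediate early 4 lower of 24, endothelial 0 of 11, and fibro-adipogenic 1 higher of 16. Smooth muscle and pericytes had 2 higher of 11, Schwann cells 1 higher of 8, erythroid 0 of 2, matrix 2 higher and 4 lower of 22 (4 and 5 adjusted over the list alone), and Notch 2 higher of 15 (1 adjusted over the list alone). Hormone signalling had 3 lower of 11 (1 higher and 3 lower adjusted over the list alone) and glucocorticoid response 6 lower of 15 (1 higher and 6 lower adjusted over the list alone). Glycolysis had 1 higher of 15, histones 1 lower of 8 and the mitochondrial genome 0 of 8. Median, mean and test differed in sign for immediate early genes (0.04, -0.11, downward), matrix genes (0.32, -0.16, upward), hormone signalling (0.17, -0.02, downward) and glucocorticoid response (0.11, -0.30, downward).

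The limma interaction test called 1620 of 10751 genes, 842 with a higher and 778 with a lower pregnancy difference in activated cells. Without adjustment 3291 had a p under 0.05. In simulated data it called 304 of 10442 unchanged genes, or 2.91%. The count was 476 with a spread by group, where Myod1 (adjusted p = 0.000225), Tnc (adjusted p = 0.000779), Vcan (adjusted p = 0.0336), Dnmt3a (adjusted p = 0.00521) and Ndufa9 (adjusted p = 0.039) were still called among the genes named here. It was 12 with array weights, where the calls of these 5 were lost as well, Myod1 (adjusted p = 0.0695), Tnc (adjusted p = 0.0923), Vcan (adjusted p = 0.186), Dnmt3a (adjusted p = 0.0966) and Ndufa9 (adjusted p = 0.155). It was 47 in the test for a value beyond 1.5-fold.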

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

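The tests of a lower share of satellite cells, of dissociation stress and of leukocytes as the source of inflammatory and other transcripts of non-activated cells, and the removal of the span trend and of the libraries with the fewest detected genes, were chosen after results were seen.

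Cell division genes were higher in activated cells of mice that were not pregnant, where the kit differed as well. Against a trend with genomic span as the whole cause stands that 97% of the 33 called cell cycle genes stayed called higher once the trend was taken out, with a median log2 change of 2.84 ± 1.19 (SD) after 3.29 ± 1.32, although 63.2% of all called genes did so, which leaves the trend open for the rest. The kit cannot be told apart from injury, since each kit was used for 1 kind of cell only: histone genes lay at -2.7 against all genes, but their members went both ways and no small RNA had a value. Activation by injury stays open for these genes as untested, beside the kit. Of 84 splits only the real one, with 7806 genes, gave as many, against at most 0 in the others by limma. In pregnant mice 1 of 84 did, with 7832 against at most 1. Mice or batches shared within a group stay open as a cause.

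In activated cells of pregnant mice oxidative phosphorylation genes fell slightly while leukocyte, matrix and fibro-adipogenic genes rose. The endothelial median (-0.13 ± 0.06, SE) lay below the leukocyte median (1.66 ± 0.18) by a log2 value of -1.79. These errors are over the genes of a list and hold no spread between libraries. The gap goes against a lower share of satellite cells that raises the markers of all other cell types alike. It cannot test a lower share that lets in some cell types more than others, with leukocyte and fibro-adipogenic markers among those that rose. A trend with genomic span may account for part of the fall, since 41.7% of the 48 calls were left after its removal, as the log2 change shrank to -0.18 ± 0.08 (SD) from -0.29 ± 0.05, and 69.2% of all 2883 calls were left. Leukocytes in the sort, which removes CD45-positive cells, are a candidate source of the leukocyte rise of 1.66, with Lyz2 as the highest marker at 1627 normalized counts and none of the 24 listed genes in another list, and an effect of pregnancy on the cells stays open as untested. Of 100 splits only the real one gave as many genes, against at most 2 in the others. Shared mice or batches stay open too.

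Inflammatory genes and NF-kB targets rose in non-activated cells of pregnant mice, with Ccl2, Cxcl1, Icam1, Tnfaip3 and Csf1 called. Immediate early genes went both ways (median -0.14 ± 0.16, SE), so dissociation stress stays open. The libraries with the fewest detected genes did not carry the inflammatory rise. Without them 109.7% of its median log2 change was left, with 4 of the 5 genes still called. Of the 8 of 24 leukocyte markers with values, the highest, Cd68, had 55.5 normalized counts, or 1.95% of the median rise of 2845 in the called genes. This level was 3.41% of the median rise of 1628 in all 301 genes that rose. That argues against leukocytes for the set unless they express its genes far above Cd68. For the 182 genes that fell, a loss of leukocytes cannot be told apart, as Cd68 in mice that were not pregnant had 137.6, or 13.33% of the median fall of 1032, and the leukocyte median of -1.06 rests on few counts. A response to pregnancy remains a hypothesis from the same data, beside sex or batch (see Uty counts). The 10 splits of 3 against 3 libraries are too few to test chance, with 483 genes in the real split and at most 0 in the others.

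The highest or lowest library stood far from the other 5 of its group in 34 of 320 groups of 6 libraries tested, or 10.6%, where chance gives about 5%. In activated_pregnant replicate 4 this held 17 times. Its normalized counts, with the range of the others, were lower for Ccne1 at 378 (644.4 to 699.2), Cks1b at 549.9 (826.7 to 907.1), Ndufs7 at 772.3 (916.9 to 1003), Nop2 at 1227 (1711 to 1998), Rpl7l1 at 1614 (2024 to 2263), Rrm2 at 2639 (4443 to 5088) and Vcan at 1193 (1765 to 2040). They were higher for Col22a1 at 900.8 (123.1 to 241.7), Cxcl10 at 3330 (1028 to 1463), Foxo1 at 2067 (1187 to 1439), Gbp2 at 3050 (1067 to 1685), Pdgfrb at 1386 (945.3 to 1045), Pi16 at 247.8 (73.42 to 131.6), Tmem204 at 211.6 (82.95 to 119.1) and Xirp2 at 85.01 (19.65 to 43.47). Its mean log2 level of the quiescence list was 11.89 (11.31 to 11.52) and of the ribosome biogenesis list 10.81 (11.15 to 11.34). Without this library 2284 genes differed by pregnancy in activated cells and 9 lists were shifted at the preset correlation. With all libraries no list was shifted with an estimated correlation.

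Activated replicate 1 stood apart 7 times, with higher counts for Cenpf at 1244 (650.7 to 868.6), Dusp4 at 699.1 (307.3 to 410.4), Enc1 at 1260 (587 to 768.9), Esm1 at 518.4 (213.1 to 294.1), Fn1 at 13910 (4303 to 7861) and Hmox1 at 1237 (845.7 to 946.8), and a lower immediate early list at 12.20 (13.05 to 13.49). Activated_pregnant replicate 3 was higher for Atp5g2 at 1456 (1342 to 1381), Bola1 at 143.9 (106.5 to 118.5) and Tmem266 at 67.63 (10.03 to 24.17), and activated_pregnant replicate 2 for Lyz2 at 3406 (707.6 to 1675) and Pecam1 at 1310 (161 to 582.4). Activated replicate 2 was higher for Atp5g2 at 1916 (1494 to 1626) and the oxidative phosphorylation list at 10.84 (10.50 to 10.63), activated replicate 5 for Angptl4 at 4909 (3512 to 3909) and the interferon list at 8.29 (7.90 to 8.03), and activated replicate 4 for the smooth muscle and pericyte list at 8.83 (8.20 to 8.40).

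By the interaction test the pregnancy difference differed between activated and non-activated cells for 54 of the 136 genes named and for 7 lists. The kit differed between these cells too, so activation cannot be told apart from it here. The difference in activated minus that in non-activated cells was positive, in log2 units, for Ifi205 (5.63), Xirp2 (5.60), H2-Ab1 (5.34), AI607873 (4.94), Tmem204 (4.58), Col22a1 (4.48), Mmp3 (4.28), Cdc6 (4.03), H2-Aa (3.97), Amacr (3.24), Lsmem1 (3.00), Birc5 (2.90), Uhrf1 (2.48), Fn1 (1.92), Ngfr (1.82), Gpam (1.79), Dnmt3b (1.64), Cspg4 (1.39), Slc7a11 (1.33), Fhit (1.25), Dnmt3a (1.20), Foxo1 (0.94), Pax7 (0.69) and Notch2 (0.50). It was negative for Spp1 (-5.79), Hspb8 (-5.25), Pgf (-4.26), Dusp4 (-4.04), Esm1 (-3.83), Lgals3 (-3.64), Tnc (-2.87), Angptl4 (-2.73), Atp5k (-2.71), Rnd1 (-2.61), Ccl2 (-2.56), Enc1 (-2.45), Sipa1l2 (-2.43), Hmox1 (-2.19), Tnfaip2 (-2.18), Cenpa (-2.17), Myod1 (-1.83), Vcan (-1.72), Cxcl1 (-1.62), Cish (-1.18), Myc (-1.06), Lox (-1.05), Cdkn1a (-0.96), Igfbp5 (-0.93), Ifi27 (-0.92), Ndufa9 (-0.84), Nop2 (-0.81), Rpl7l1 (-0.79), Icam1 (-0.73) and Atp5g2 (-0.53). The median over a list was 2.53 for leukocytes, 0.35 for DNA methylation, -0.84 for interferon response, -0.40 for inflammatory genes, -0.34 for oxidative phosphorylation, -0.65 for ribosome biogenesis and -0.40 for ribosomal proteins. Of 100 splits that permuted pregnancy within activation, 3 gave as many genes, the real one with 1620 included. This share is low, but the highest of the others gave 1654. The non-activated libraries allow only 10 splits, too few to exclude chance for the count. Nor is it excluded for single genes, as 2.91% of unchanged genes were called in simulated data.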

How the results depend on the processing

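Recomputed size factors, voom, the spread by group, the removal of the span trend and the removal of the libraries with the fewest detected genes were chosen after the data were seen. The counts of changed genes stayed within 1.5 times those reported with quantile normalization, no filter, pseudocounts of 0.1 and 10, recomputed size factors, voom and removal of the span trend, in all 5 comparisons. Quantile normalization moved the median log2 change of all genes in activated against non-activated cells from 0.169 to 0.014, and in pregnant mice from 0.21 to 0.006. Of the genes named, 34 of 44 in mice that were not pregnant and 23 of 35 in pregnant mice kept their direction and side of the threshold between activated and non-activated cells in every setting run, as did 20 of 45 and 7 of 53 in the pregnancy comparisons of non-activated and activated cells and 4 of 27 in the interaction.

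In the test for a change beyond 1.5-fold the counts were 5110, 4984, 39, 13 and 47, since it asks each gene to exceed that fold beyond its error, which depends on the spread as well as on the size of the change. With all 4 groups in the fit, which sets one spread for both kits, the pregnancy counts were 2485 in non-activated and 578 in activated cells. The count in non-activated cells was 117 without the libraries with the fewest detected genes, where each group keeps 2 libraries, and 237 to 441 with 1 library left out, with 4 to 7 lists shifted. The interaction count was 12 with array weights and 476 with a spread by group, of which 474 were among the 1620. With an estimated correlation 0 lists were shifted in each comparison, and with fry, which asks another question, 22 and 18 in the activation comparisons and 2 each in non-activated cells and the interaction. For the other settings below the cause was not tested. In pregnant mice 15 lists were shifted between activated and non-activated cells with the span trend taken out. The correlation across genes of the pregnancy changes was 0.199 for genes above the median of expression, and that of the activation changes 0.946 there and 0.79 with the span trend taken out.

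Directions were reversed in the activation comparisons with the span trend taken out for Lama2 (0.81) and Myf5 (-0.70) in mice that were not pregnant, and for Myod1 (-0.40), Pax7 (0.11), Myf5 (-0.72) and Dnmt3a (0.47) in pregnant mice. The immediate early list was then shifted downward in both (adjusted p = 9.05e-05 and 0.00026), and the mitochondrial genome list upward by pregnancy in activated cells (adjusted p = 0.0242). The DNA methylation list of pregnant mice moved upward by fry (adjusted p = 0.00873).

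A block for the replicate number gave 7411, 7403, 568, 2177 and 1204 genes in the 5 comparisons, but the numbers do not pair the samples, whose same-number correlations ran from -0.172 to 0.138. The count models named in the plan, DESeq2's test and size factors and the interaction's other fit among them, were not run. Depth sets the low end, where a count of 0 allows up to 3 counts. In simulated data the fit of 3 against 3 libraries recovered 9% of genes changed 1.5-fold and that of 6 against 6 libraries 91%, and whether depth has a part in this was not tested.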

Other observations

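The genes named first were chosen after their values were seen, from the 162 genes called by limma in both pregnancy comparisons. Single genes that rose in pregnant mice in non-activated and in activated cells included H2-D1 by log2 changes of 0.84 and 0.45, H2-Q4 by 0.90 and 0.52, and Tapbp, which loads peptides on class I molecules, by 0.82 and 0.40. Others were Plau, a plasminogen activator, at 1.47 and 0.26, its receptor Plaur at 1.70 and 0.33, Fmod, fibromodulin, at 2.35 and 1.05, and Reln, reelin, at 1.89 and 1.53. Further ones were Rel at 0.72 and 0.81, Tnip1 at 0.79 and 0.68, Jak2 at 0.83 and 0.44 and Osmr, the receptor of oncostatin M, at 0.70 and 0.51 (adjusted p from 0.000102 to 0.0425 for these last 4). None of these genes stands for a pathway, as no list was fixed or tested for them.

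Among genes lower in pregnant mice in both kinds of cells were Parp1 and Xrcc5, which act in DNA repair, by log2 changes of -0.97 and -0.33, and of -1.11 and -0.37, whereas Rad52, another gene of DNA repair, rose by 1.26 and 0.26. Sox9, a transcription factor of cartilage and progenitor cells, was called in opposite directions, at 1.18 in non-activated and -0.35 in activated cells, as was Adamts20 at -1.27 and 0.83.

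The sex check listed Xist, Tsix, Ddx3y and Eif2s3y without a value. Counts of Y-linked Uty were 51, 56 and 56 in non-activated libraries of mice not pregnant and 2 to 8 in each of the other 15, against 1406 to 6615 for its X-linked relative Kdm6a. Those of Y-linked Kdm5d were 28, 128 and 75 in the same 3 libraries, 79, 3 and 9 in non-activated libraries of pregnant mice, and 4 to 30 in activated ones. Uty, unlike Kdm5d, parted pregnant from other mice in non-activated cells, so sex or batch stays open there and in the interaction.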
